A study of Rattus norvegicus with 18 samples.

How the data were processed

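Total RNA from kidneys of Dahl S rats (3 samples) and congenic rats (3 samples) had been hybridised to 3 array types each, per the labels. Groups and sample numbers were taken from the sample titles, and the arrays of a sample were joined across array types by the tag in its label. The deposited values are intensity values, 1 per probe set on a linear scale. From the values, the authors' deposited intensities were scaled so that the mean after trimming 2% at each end lay between 150.1 and 150.2 on each array. The software that summarised the probes is not given in the sources used here. Because the arrays of each type had the same trimmed mean, the values were used without further scaling, a rule set before the data were examined.

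For each array type, values below the 10th percentile were raised to it (3.1, 6.8 and 4.9 signal units on types A, B and C), and log2 was taken. The 59 control probe sets of each type were left out, which left 26202, and probe sets whose mean log2 signal over the 6 samples was below the 40th percentile of their type were not tested, which left 15721. The GEO platform annotation gave 1 gene symbol for 18178 probe sets, several for 391 and none for 7633. Probe sets with several symbols were not named. Of the 18178, 18122 (99.7%) matched a gene of the GRCr8 assembly table by gene ID, and 0 symbols needed updating. That table gave chromosomes and gene order; the sources used here name no genome build, so no positions are given.

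The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), congenic minus Dahl S, in 1 fit per array type. The Benjamini-Hochberg adjustment ran over the probe sets of all array types together, with a threshold of 0.05. Genes were represented by the probe set with the highest mean log2 signal over the 6 samples. The 21 gene lists were fixed before the data were examined and tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, on lists with at least 5 tested members, with the adjustment over the lists. The estimated correlation and fry, which asks whether a list's genes move one way on balance, were run as alternatives. Chromosome 9 was compared with the other chromosomes by a two-sided Fisher's exact test on genes with an unadjusted p under 0.01. A planned count of such genes in runs of 20 consecutive chromosome 9 genes is not reported, because with 1 such gene the highest count is fixed at 1. Control ratios were compared by exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

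Named genes followed a rule written before the data were examined: up to 15 genes per direction past the threshold, and where fewer than 10 passed, the genes with the smallest unadjusted p up to 10 per direction, said not to pass. The rule added, for each list, the members past the threshold or otherwise the 2 with the smallest p, and chromosome 9 genes with a p under 0.01. It named 56 genes. Other list members and neighbours of Resp18 that are named were chosen after their values were seen.

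The fit was tested on simulated data with the means and spread of the 15721 tested probe sets, each sample drawn independently. Of 67, 67 and 66 probe sets changed by 1, 2 and 3 log2 units it called 7, 36 and 46, with 4 false calls. In 20 simulations without correlation between genes, camera with the preset correlation made 0 false calls among 420 list tests. The estimated correlation of the injury list in the data was 0.071, so this does not show how often false calls arise with correlated genes. A shift of -0.35 log2 units given to the injury list was called in 20 of the 20 with the preset correlation and in 7 with the estimated one.

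The alternatives covered the floor (none, 25th percentile), the filter (none, 60th percentile), quantile normalization, median scaling, eBayes without the trend or with robust estimation, the sample number as a block, each sample left out, adjustment within each array type, an adjusted p of 0.1, other p thresholds for chromosome 9 and the mean of a gene's probe sets. Those without both samples numbered 1 and with a term for them were chosen after seeing the data.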

Results

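Kidney transcript levels were measured in 2 rat strains. The Dahl salt-sensitive (S) rat is an inbred strain whose blood pressure climbs on a high-salt diet. The congenic strain carries, on the S background, a segment of chromosome 9 from a salt-resistant (R) rat, and per its labels that segment holds a blood pressure quantitative trait locus, a region whose alleles are associated with blood pressure. The comparison asks which kidney transcripts differ between strains that share most of their genome. Each strain had 3 samples of total kidney RNA, each with its own tag, and each sample was hybridised to 3 array types, called A, B and C here, for 18 arrays in all. The arrays give 1 signal per probe set, a group of short probes for 1 transcript. The 3 types held 8799, 8791 and 8789 probe sets, 59 controls included in each. Median signals were 34.8 to 45.9 on type A, 60.4 to 78.5 on type B and 61.1 to 75.6 on type C. The number of arrays limits the precision. No label says outright that the tags are separate animals, so p-values measure the spread between these samples, which may be technical. The labels used here give no diet or age.

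Among genes represented by 1 probe set with a single symbol, the strain difference with the smallest p was in Resp18, a chromosome 9 gene. Resp18 encodes a protein of the secretory pathway of endocrine and neuroendocrine cells. Its signal was 201.6, 141.8 and 184.3 in the Dahl S samples and 43.1, 18.9 and 10.6 in the congenic samples, 8.48-fold lower in the congenic strain (log2 difference -3.08, SE 0.50, n = 3 per strain). Its unadjusted p in limma was 0.000238, and it did not pass the adjusted threshold (adjusted p = 0.9997). A second probe set made from the same transcript sequence gave a log2 difference of -3.16 (SE 0.69). Other genes with lower congenic signal were Clu, the secreted chaperone clusterin (-1.09 log2, SE 0.19), Prrx1, a mesenchymal transcription factor (-1.68, SE 0.34), Spp1, the matrix protein osteopontin (-1.04, SE 0.21), and Ccnb1, the mitotic cyclin B1 (-1.60, SE 0.38). Higher congenic signal was measured for Nr4a3, an immediate early nuclear receptor (+2.29, SE 0.53), and for Slc4a4, the basolateral sodium bicarbonate cotransporter of the proximal tubule (+0.68, SE 0.17). None of these passed the adjusted threshold. Some signals were below 21.2, the level of the filter on type A, and were not shown to be above background: Resp18 and Ccnb1 in congenic samples 2 and 3 and Nr4a3 in all 3 Dahl S samples, so the sizes of these differences are uncertain.

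In the whole comparison limma called 0 of 15721 tested probe sets at an adjusted p of 0.05, in either direction. At an unadjusted p under 0.05 there were 391 probe sets where chance alone would give 786, and under 0.01 there were 54 where chance would give 157. Of the 54, 18 were higher and 36 lower in the congenic strain, and 19 had no single gene symbol and were not named. Among 8168 genes represented by 1 probe set each, 26 had an unadjusted limma p under 0.01, 8 higher and 18 lower. The 3 congenic values did not overlap the 3 Dahl S values in 1113 probe sets (7.08%), against the 10% that chance gives. The median 95% confidence interval of a log2 difference extended 0.68 to either side. In simulated data with the spread of these arrays the same procedure called 10.4% of probe sets changed by 1 log2 unit, 53.7% of those changed by 2 and 69.7% of those changed by 3. There 67, 67 and 66 probe sets were changed at once, which eases the adjusted threshold. With few changed probe sets the shares called would be lower. Each simulated sample was also drawn independently, so the simulation lacks the split by sample number that both strains share, described next. The shares called may therefore not hold for these arrays. The samples numbered 1 stood apart from those numbered 2 and 3 in both strains, and with a term for that split, chosen after seeing the data, 0 probe sets passed and 123 had an unadjusted limma p under 0.01. Without congenic sample 1 that number was 113.

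The genes with the smallest p beyond these were all measured without overlap between the strains, and none passed the threshold. On the lower side they were Triobp, an actin-binding protein (geometric mean signal 82.3 against 164), Dcn, the matrix proteoglycan decorin (-0.69 log2, SE 0.17), Hrh3, a histamine receptor (-1.09, SE 0.30), Efemp2, the elastic fibre protein fibulin-4 (-0.72, SE 0.19), and Marcks, a substrate of protein kinase C (-0.86, SE 0.24). On the higher side they were Rrp15, a ribosome biogenesis factor (+1.60, SE 0.44), Sox17, an endothelial transcription factor (+1.27, SE 0.36), Eci3, an enoyl-CoA isomerase (+0.56, SE 0.16), Arcn1, a coatomer subunit (+0.71, SE 0.21), Asgr1, the asialoglycoprotein receptor (+1.68, SE 0.47), Nbr1, an autophagy receptor (+0.63, SE 0.19), Asb1, a SOCS box protein encoded on chromosome 9 (+1.45, SE 0.44), and Acbd4, an acyl-CoA binding protein (+0.97, SE 0.31). Asgr1 in Dahl S sample 1 and Asb1 in Dahl S samples 2 and 3 were also below the filter level of 21.2. Several genes had probe sets that disagreed. A second Prrx1 probe set differed by +0.06, a second Sox17 probe set by +0.18, a second Nbr1 probe set by +0.19, and the 6 Marcks probe sets ranged from -1.05 to +1.03, whereas the 3 Slc4a4 probe sets read +0.50, +0.68 and +0.69 and the 5 Dcn probe sets read -0.19 to -1.06. The Dcn probe set at -1.06 was at the floor of type A (3.1) in congenic sample 2, so the size of its difference is uncertain.

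**Figure D1:**
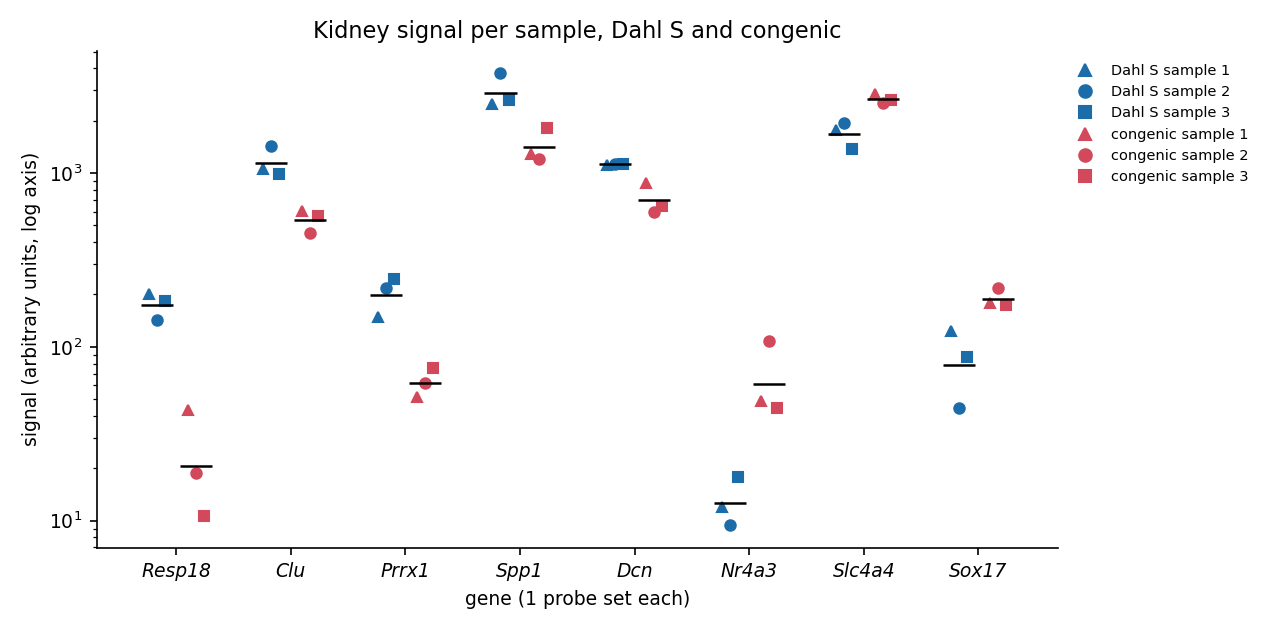
Signal per sample (arbitrary units, log axis) of 8 genes with a small unadjusted p, 1 probe set each, in 3 Dahl S samples (blue) and 3 congenic samples (red); marker shapes give the sample number and black bars the geometric mean of 3 samples. For Resp18 the Dahl S samples lie between 141.8 and 201.6 and the congenic samples between 10.6 and 43.1, and no gene shown passed the adjusted threshold.

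The introgressed segment lies on chromosome 9, which raises the question of whether genes on that chromosome stand out. Resp18 was the 1 gene of 319 tested on chromosome 9 with an unadjusted limma p under 0.01 (0.313%), against 25 of 7823 on other chromosomes (0.320%). Fisher's exact test gave an odds ratio of 0.981 (95% interval 0.0238 to 6.03, two-sided p = 1). Asb1, also on chromosome 9 (+1.45 log2, SE 0.44), missed the limit narrowly, so the count depends on where the limit is set. With so few genes the interval does not exclude a several-fold excess. The borders of the segment are not given in the sources used here, so chromosome 9 genes outside it were counted too. The test therefore cannot tell whether genes inside the segment stand out. Of the 20 tested genes nearest to Resp18 in the gene order of the GRCr8 assembly, 10 on each side, 1 had an unadjusted limma p under 0.05: Tuba4a, an alpha-tubulin (+1.11 log2, SE 0.47). Tuba4a was itself below the filter level of 21.2 in Dahl S samples 2 and 3. The tested genes next to Resp18 on either side, Ptprn and Dnpep, differed by +0.01 and +0.04, and Stk16, next to Tuba4a, by -1.29 (SE 0.80).

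Genes of tissue injury, inflammation and fibrosis, a list fixed before the data were examined, were lower as a group in the congenic kidneys. Of 33 tested members 28 were lower and 5 higher, with a median log2 difference of -0.35 (limma camera with a preset correlation of 0.01, adjusted p = 5.23e-09 over 21 lists). With an estimated correlation the adjusted p = 0.168, so the call was lost. Over all genes 0 members passed limma's threshold, and adjusted over the list alone 3 did, all lower: Clu, Spp1 and Dcn. The growth factor-induced matrix protein Ccn2 (-1.35, SE 0.40), the neutrophil gelatinase-associated lipocalin Lcn2 (-1.60, SE 0.49) and the collagen chain Col1a1 (-0.38, SE 0.13) had unadjusted limma p values of 0.00717, 0.0114 and 0.0178. Lcn2 was below the filter level of 21.2 in congenic sample 2, so the size of its difference is uncertain. All 4 Col1a1 probe sets lay between -0.36 and -0.38. Icam1 (+0.30) and Egf (+0.18) were among the 5 members with higher congenic signal. The list's per-sample medians, relative to the means of all samples, were 0.11, 0.35 and 0.18 in the Dahl S samples and -0.06, -0.24 and -0.15 in the congenic samples. Without both samples numbered 1 the median was -0.34, and without Dahl S sample 2 it was -0.23. The call with the preset correlation held with each sample left out in turn.

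Markers of leukocytes and of smooth muscle and stroma were also lower as groups. Of 21 leukocyte genes 17 were lower (median -0.30, camera adjusted p = 0.00700, and adjusted p = 0.320 with an estimated correlation), among them Coro1a, an actin regulator of blood cells (-0.81, SE 0.33), and the macrophage protein Cd68 (-0.43, SE 0.19). Of 14 smooth muscle and stroma genes 10 were lower (median -0.26, camera adjusted p = 0.0145, and adjusted p = 0.320 with an estimated correlation). Adjusted over the list alone 1 stroma gene passed in limma, Dcn, and 0 leukocyte genes did. The stroma list shares 4 tested genes with the injury list, Dcn, Col1a1, Col3a1 and Lum, all lower, and the leukocyte list shares 0. The stroma genes outside the injury list were mixed. Acta2 (-0.67), Tagln (-0.38), Myl9 (-0.35), Pdgfra (-0.20), Pdgfrb (-0.07) and Mylk (-0.001) were lower. Actg2 (+0.07), Tpm1 (+0.15), Myh11 (+0.50) and Tpm2 (+0.76) were higher, and Actg2 and Myh11 had samples below the filter level. Camera was not run on the stroma list without the shared genes. The leukocyte call was lost without Dahl S sample 2 (median -0.19) or congenic sample 3 (-0.24), and the stroma call without Dahl S sample 2 (-0.24), Dahl S sample 3 (-0.19) or congenic sample 2 (-0.07).

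Genes of renal sodium and water transport and markers of the proximal tubule were higher as groups. Of 30 transport genes 22 were higher (median +0.11, camera adjusted p = 0.00438, and adjusted p = 0.168 with an estimated correlation). Slc4a4 and Stk39, the kinase SPAK that phosphorylates sodium chloride cotransporters (+1.54, SE 0.58), were the 2 members with an unadjusted limma p under 0.05, and adjusted over the list alone 0 passed. The 3 tested Stk39 probe sets read -0.41, +0.42 and +1.54. The list's median was +0.05 without Dahl S sample 1 and +0.17 without congenic sample 1, and the call with the preset correlation held in both. The sodium channel subunits Scnn1a (-0.10), Scnn1b (-0.08) and Scnn1g (-0.05) and the thiazide-sensitive cotransporter Slc12a3 (+0.10) differed by less than 1 SE, and Scnn1b was below the filter level in congenic sample 2. Of 25 proximal tubule genes 20 were higher (median +0.13, camera adjusted p = 0.00901, and adjusted p = 0.255 with an estimated correlation), such as Pck1, the gluconeogenic carboxykinase (+0.31, SE 0.16). Against that direction, the phosphate cotransporter Slc34a2 had the smallest p of the list (-0.94, SE 0.39), and adjusted over the list alone 0 passed. Slc34a2 read 204.9, 59.6 and 116.6 in congenic samples 1, 2 and 3, against 200.9 to 231.4 in the Dahl S samples. The proximal tubule call was lost without Dahl S sample 3 (median +0.11) or congenic sample 3 (+0.12), and under quantile normalization (+0.09) or median scaling (+0.16).

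**Figure D2:**
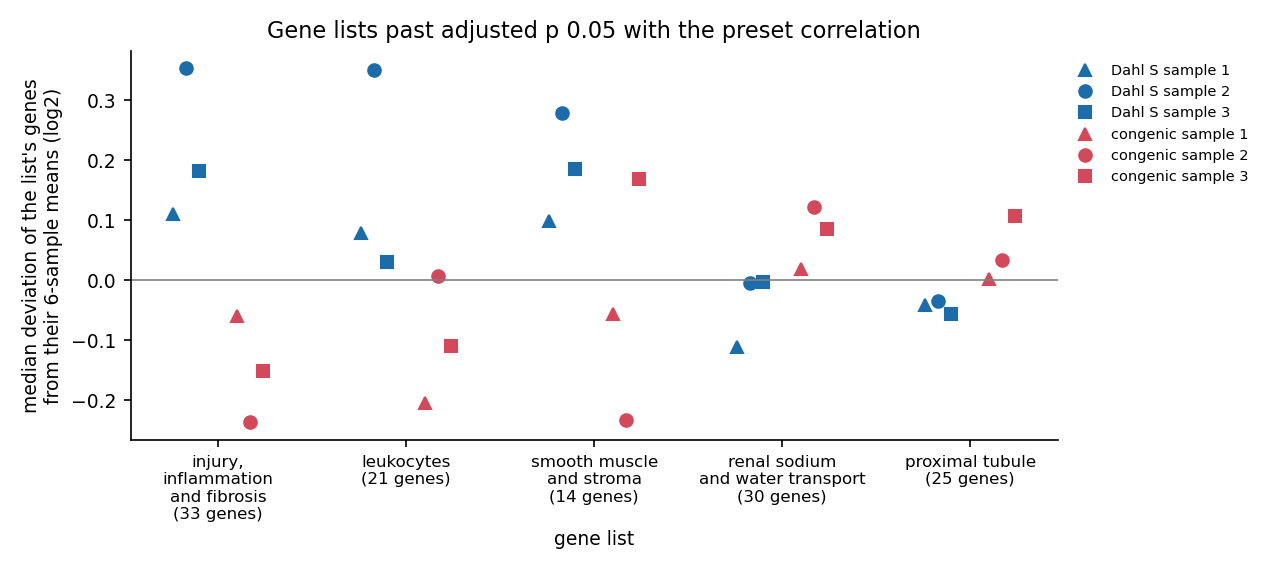
Median deviation of each list's genes from their means over 6 samples (log2 units), per sample, for the 5 lists past the threshold with the preset correlation; blue marks Dahl S and red congenic samples, and shapes give the sample number. The injury list separates the strains, from 0.11 to 0.35 in Dahl S and from -0.24 to -0.06 in congenic samples, while in smooth muscle and stroma congenic sample 3 (0.17) lies among the Dahl S samples.

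The other lists of pathways tied to blood pressure did not pass, and their medians lay within 0.13 log2 units of 0. Renin-angiotensin and kallikrein-kinin genes had 9 of 13 members higher (median +0.10, camera adjusted p = 0.277), with the angiotensin-converting enzyme gene Ace at +0.67 (SE 0.37) and the kininogen Kng2 at -0.92 (SE 0.37). Vasoactive peptide, nitric oxide and adrenergic genes had 14 of 25 higher (median +0.10, camera adjusted p = 0.741), with the receptor kinase Grk4 at -0.54 (SE 0.33) and the adrenergic receptor Adra2a at +0.90 (SE 0.60), whose other probe sets read +0.01 and +0.04. Arachidonate, eicosanoid and steroid metabolism had 15 of 22 higher (median +0.13, camera adjusted p = 0.418), with the vitamin D hydroxylase Cyp24a1 at -0.66 (SE 0.30) and the epoxide hydrolase Ephx1 at +0.42 (SE 0.21). Oxidant and antioxidant enzymes had 23 of 36 higher (median +0.07, camera adjusted p = 0.372), with the oxidase subunit Cyba at -0.24 (SE 0.14) and the chromosome 9 gene Gsta3, a glutathione transferase, at +0.30 (SE 0.18). In each of these 4 lists 0 members passed limma adjusted over the list alone.

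Metabolic, clock and immune lists did not pass either. Fatty acid oxidation had 21 of 35 genes higher (median +0.01, camera adjusted p = 0.164), with Acadm at +0.24 and Acox2 at -1.02, and oxidative phosphorylation had 22 of 32 higher (median +0.06, camera adjusted p = 0.156), with Atp5me at +0.21 and Uqcrb at +0.55. Circadian clock genes had 5 of 9 higher (median +0.14, camera adjusted p = 0.741), with Bmal1 at +0.65 and the chromosome 9 gene Npas2 at -0.83. Immediate early and heat shock genes had 15 of 23 lower (median -0.10, camera adjusted p = 0.315), Jun among them (-0.66), whose other 3 probe sets read -1.50, -0.02 and +0.05. Against that direction, Nr4a3 had the smallest p of the list (+2.29, SE 0.53), with all 3 Dahl S samples below the filter level. Antigen presentation had 14 of 21 lower (median -0.14, camera adjusted p = 0.132), among them the immunoproteasome subunit Psmb9 (-0.81, SE 0.28) and its regulator Irf1 (-0.56, SE 0.24). Acox2, Uqcrb, Bmal1 and Npas2 had samples below the filter level of their array type, so the sizes of their differences are uncertain. In each of these 5 lists 0 members passed limma adjusted over the list alone.

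Of the other nephron segments, thick ascending limb and distal convoluted tubule markers were higher in 10 of 13 genes (median +0.11, camera adjusted p = 0.156), with Sostdc1 at +0.30 and Trpm7 at +0.71, and collecting duct markers in 10 of 15 (median +0.05, camera adjusted p = 0.221), with Slc14a2 at +0.44 and Slc26a4 at +0.27. Glomerular markers were higher in 6 of 10 genes (median +0.10, camera adjusted p = 0.676), with Podxl at +1.08 and Ptn at -0.62. The Podxl signal was 55.6 in Dahl S sample 3 and 266.1 to 365.7 in the other samples, so its difference rests largely on that sample. Trpm7 and Ptn each had 1 sample below the filter level of their array type, so the sizes of their differences are uncertain. Endothelial markers had 8 of 14 higher (camera adjusted p = 0.957), with a median of +0.04, a mean of -0.03 and a direction of down in camera; Emcn was at +0.36 and Pecam1 at -0.40. Blood cell genes were lower in 5 of 6 (median -0.44, camera adjusted p = 0.213), with Dahl S sample 3 far above the rest: its signal for the alpha-globin Hba-a1 was 36676, against 5917 to 11704 in the other samples, and Hba-a3 showed 212.9 there. Without Dahl S sample 3 the log2 differences of Hba-a1 and Hba-a3 were +0.02 and +0.03, against -0.67 and -0.58 with it. Without both samples numbered 1, a comparison chosen after seeing the data, the blood cell list (median -1.01, camera adjusted p = 0.0148) and the thick ascending limb and distal convoluted tubule list (median +0.23, camera adjusted p = 0.0438) passed with the preset correlation. Neither passed there with an estimated correlation (adjusted p = 0.613 and 0.599), and Dahl S sample 3 (per-sample median 1.49) again stood above the other 3 samples in the blood cell list (-0.78 to -0.16 in congenic samples 2 and 3, -0.41 in Dahl S sample 2). Markers of neighbouring tissues did not pass. Adrenal markers had 4 of 6 higher (median +0.12, camera adjusted p = 0.356), with Fdx1 at +0.22 and Th at +0.27. Fat markers had 5 of 9 lower (camera adjusted p = 0.741), with a median of -0.09 and a mean of -0.10 but a direction of up in camera, and Lpl at +0.38, whose other probe sets read +0.60 and -0.07.

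Ratios of control probe sets, a measure of RNA quality, overlapped between the strains. The mean log2 ratio of 3 prime to 5 prime signal differed between congenic and Dahl S by -0.12 for GAPDH (exact permutation p = 0.5) and +0.09 for beta-actin (exact permutation p = 0.7), two-sided, where 3 samples against 3 cannot give a p under 0.1. The beta-actin ratio was 1.16 to 1.61 on the 6 arrays of the samples numbered 1 and 2.04 to 2.66 on the other 12 arrays. The hexokinase ratio averaged over array types was 2.53 and 2.60 in the samples numbered 1 and 8.66 to 10.5 in the others.

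**Figure D3:**
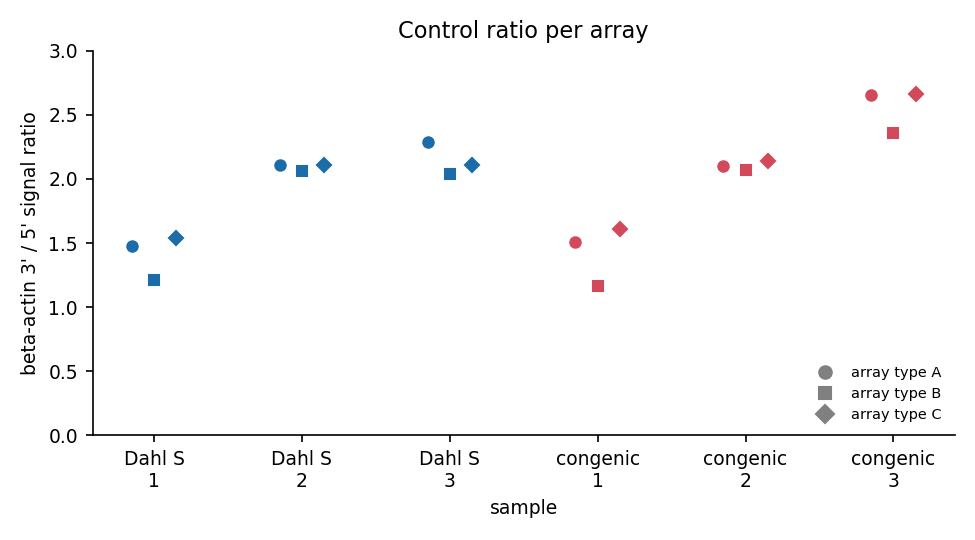
Ratio of 3 prime to 5 prime beta-actin signal on each of the 18 arrays, by sample (3 Dahl S in blue, 3 congenic in red) and array type (marker shape). In both strains the sample numbered 1 has ratios of at most 1.61, below the lowest ratio of the other samples, 2.04.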

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

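The count of 0 probe sets past the limma threshold stayed at 0 under every alternative run. Of 993 log2 differences of the 56 named genes under alternatives, 991 kept their direction, 0 passed an adjusted limma p of 0.05 (lowest 0.245), and 2 reversed: Hba-a1 and Hba-a3 without Dahl S sample 3 (0.0247 and 0.0292), with ranges of -1.11 to 0.0247 and -0.991 to 0.0292 when 1 sample was left out. Scaling moved the median of all probe sets to at most 0.02 log2 units. Probe sets with an unadjusted p under 0.01 numbered 54, against 129 without the filter, which tests more probe sets, 35 with median scaling, 48 to 113 with 1 sample left out (113 without congenic sample 1), and, in alternatives chosen after seeing the data, 98 without both samples numbered 1 and 123 with a term for them. The replicate block gave 146 and kept 0 probe sets and 5 lists past the threshold. The sample numbers were not taken as pairs, because no label says that equal numbers were litter mates or a batch. Not every same-numbered correlation of deviations was over 0.1: those of numbers 1, 2 and 3 were 0.45, 0.08 and 0.18 over all array types and 0.53, -0.09 and 0.16 on type A, but 0.36, 0.16 and 0.14 on type B and 0.49, 0.18 and 0.30 on type C. Of the 6 samples, 4 correlated best with their own number over all types, 2 on type A and 6 on types B and C, a hint of pairing from the data, not the design. The 5 lists became 0 with an estimated correlation and 0 with fry, 3 to 6 with 1 sample left out (3 without Dahl S sample 3 or congenic sample 3), and 7 without both samples numbered 1, where blood cells and thick ascending limb also passed. The medians do not move under those tests, and the adjusted p values with an estimated correlation and fry were 0.168 and 0.154 for injury (-0.35), 0.320 and 0.303 for leukocytes (-0.30), 0.320 and 0.303 for stroma (-0.26), 0.255 and 0.154 for proximal tubule (+0.13) and 0.168 and 0.154 for sodium and water transport (+0.11). The proximal tubule list did not pass under quantile normalization (+0.0884) or median scaling (+0.16). With 1 sample left out the medians ran from -0.38 to -0.23 for injury, -0.43 to -0.19 for leukocytes, -0.28 to -0.0669 for stroma, +0.0980 to +0.16 for proximal tubule and +0.05 to +0.17 for transport. The chromosome 9 odds ratio (0.981) went above 1 with the floor at the 25th percentile (1.89), without the filter (1.02), with quantile normalization (2.96), median scaling (1.53), eBayes without the trend (2.31), p under 0.001 (12.3), every probe set (2.09) and without both samples numbered 1 (1.80), and ran from 0.876 to 1.44 with 1 sample left out. The odds ratio was 0 with the filter at the 60th percentile, 0.787 at p under 0.05, 0.845 with the replicate block and 0.891 with a term for the samples numbered 1. Fisher's exact p lay between 0.0950 and 1 in all of these. The control ratio difference (-0.02, the mean of GAPDH and beta-actin) ran from -0.17 to 0.18 with 1 sample left out, with exact permutation p values of at least 0.5. Except where stated, the cause was not tested.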

Other observations

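The tests of splits, of the samples numbered 1, of RNA integrity, of Resp18 and of stroma and leukocyte markers outside the injury list were chosen after the results were seen; the test of the 8 tubular members was chosen before, and its repeat without 3 of them after. Several members of the injury list that did not stand out alone lay on the lower side in the congenic samples. Among matrix genes, Col5a2 (-0.57), Mmp2 (-0.83), Col1a2 (-0.39), Col3a1 (-0.33), Fn1 (-0.26) and Col4a2 (-0.41) were lower, and so were the mesenchymal filament gene Vim (-0.44) and the collagen-binding proteoglycan Lum (-0.35), each with an unadjusted limma p above 0.05. The Mmp2 difference rests largely on congenic sample 2, with a signal of 32.8 against 91.1 to 145.1 in the other samples. In antigen presentation the class II chaperone Cd74 (-0.23) and Psmb8 (-1.28) were lower, while B2m (+0.27) and RT1-S3 (+0.42) were higher. The smooth muscle genes were mixed, with Acta2 at -0.67 and Myh11 at +0.50. Lum and Myh11 had samples below the filter level of their array type, so the sizes of their differences are uncertain.

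Injury, inflammation and fibrosis genes had a median of -0.35 over 33 genes, below each of 10000 random lists of the same size and signal. That comparison ignores correlation between members. The list did not pass in camera with an estimated correlation (adjusted p = 0.168) or in fry (adjusted p = 0.154). Correlation between members need not be the reason. The transport list had an estimated correlation of -0.0038, below the preset 0.01, and its call was lost too. In simulations without correlation, a shift of -0.35 in the injury list was called in 20 of 20 with the preset correlation. With the estimated one it was called in 7. The injury list's difference did not rest on the samples numbered 1, since its median without them was -0.340. A batch shared by them lies in both strains and cancels in the strain difference, so leaving them out cannot test it. RNA integrity, as far as the mean of the GAPDH and beta-actin ratios measures it, differed little between the strains, by -0.02 log2 units. In that mean -0.12 for GAPDH and +0.09 for beta-actin offset each other. The hexokinase ratio, not part of it, differed by -0.13 (exact permutation p = 0.6). Within strains the samples numbered 1 differed from the others by -0.54 in the mean of GAPDH and beta-actin. The list differed there by a median of 0.0421 (mean 0.03, SE 0.08 over members, which treats correlated genes as independent). The median was -0.17 in Dahl S and 0.17 in congenic samples, opposite directions that each rest on 1 sample. Whether the list follows the ratio therefore cannot be told from these contrasts. Fewer leukocytes and stromal cells in the congenic samples stay open: the bound set beforehand against this was met by 8 tubular members (median -0.522), but Spp1, Cd44 and Lcn2 are also expressed by leukocytes, and the 5 others had a median of -0.21, with 6.62% of random lists at or below it. For the members outside the tubular set, 31 stroma and leukocyte markers not in the list had a median of -0.150, which 0.8% of random lists reached but which missed the bound set for this explanation, so cell composition and lower injury-related expression with the R segment, a hypothesis, cannot be told apart.

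Resp18 may differ because of a strain sequence variant under the probes, if it lies in the segment, where the congenic strain carries R alleles. Whether the R and S sequences differ under these probes is not given in the sources used here. Its probe sets differed by 0.0754 log2 units, but both come from 1 transcript sequence, so a variant and lower expression cannot be told apart. That the segment changes several neighbouring genes cannot be told either: the 20 nearest tested genes had a median absolute t at the 95.7th percentile of runs on other chromosomes, the nearest 10 at the 89.4th and the nearest 40 at the 20.8th. Whether Resp18 lies inside the introgressed segment is not given in the sources used here.

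The samples numbered 1 stood apart in both strains, with positive weights (0.57 and 0.58) on a first principal component holding 35.6% of the variance, where the other 4 samples had negative ones. An RNA or labelling batch is a candidate explanation: the highest beta-actin 3 prime to 5 prime ratio of their arrays was 1.606, below the lowest of the others, 2.04. No biological explanation was tested for this split, as no label names one.

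The 6 samples can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. With 0 probe sets past the limma threshold, all 10 splits, the real one included, gave as many (highest other 0). For probe sets with an unadjusted p under 0.01, 8 of 10 splits gave at least the real 54 (highest other 507), and the 4 splits that put both samples numbered 1 on one side gave 208 to 507, against 33 to 69 in the rest, which points to a structure of the samples. For lists past the threshold 1 of 10 splits, the real one, gave 5 (highest other 4). For chromosome 9, all 10 splits had a Fisher's exact p no higher than the real 1 (lowest other 0.373).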
